A study of Mus musculus with 3 samples.

How the data were processed

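ChIP-seq for p65, p50 and input DNA was made from KLA-treated bone marrow-derived macrophages of C57BL/6J mice, with 1 library per group. Per the labels, 2 micrograms of each antibody were used. A peak list for p65, one for p50 and 1 table of merged peaks were used. The input library enters only through the peak lists, which give its tags at called peaks.

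Reads were aligned with Bowtie2 to mm10 and analysed with HOMER, per the submitters' processing notes, with versions not given in the sources used here. Peaks of 200 bp were called per library with 1 tag per position, at least 4-fold over input and over the surrounding 10 kb, per the file headers. The headers also required a Poisson p-value of 1.00e-04 over each of these. In the peak lists the tag signal per peak, scaled by the authors to a total of 10000000 tags (normalised tags), stands beside a score (the tags used in calling), a focus ratio as a fraction, fold ratios over input and surroundings, and a p-value for each, all as deposited. The authors set input counts of 0 to 0.5 in the fold, per the values. Scores and folds describe peaks within their own list. In the merged table the authors joined overlapping peaks, counted the tags of each library and scaled them to 10000000, which gives a signal per merged peak, per the file headers. The nearest start site, feature and repeat are the authors' annotation.

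Multiplied by the library totals, 100% of the merged table's values came out whole within 0.05 tags, so whole tags were recovered for 27323 merged peaks. The totals were 11399666 tags for p65 and 16042404 for p50. The headers' tag density times their genome size gives 2.55 M tags left at 1 tag per position for p65 (22.3%) and 7.76 M for p50 (48.4%). Repeated tags are not independent molecules, so counting intervals and floors, which cover counting error only, are too narrow, more so for p65. A count of 0 allows up to 3 counts, or 2.63 normalised tags for p65 and 1.87 for p50. The input depth implied by the deposited scaled signals was 2.32 M tags, well below the average depth per library that the labels state, and the reason is not known. At 93.0% of p65 and 92.8% of p50 peaks the input had no tag, so folds over input there restate the tags of the peak over a constant and are not used as a measure of strength.

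Overlap was computed with bedtools 2.31.1 (at least 1 bp) and compared with 100 random placements. Per merged peak, the log2 ratio of p65 to p50 used a pseudocount of 1 normalised tag. A peak with at least 16 normalised tags in the higher library was called leaning when the ratio was at least 2 either way and its 95% Clopper-Pearson counting interval excluded 1. The interval removed 0 calls. Folds in the text are ratios of scaled tags without pseudocount. Near a start site means within 1 kb. Shares have Wilson intervals over peaks, and medians have bootstrap intervals (1000 draws), and peaks are not replicates.

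Genes were named by a rule fixed before the data were examined. Peaks took the name of their nearest gene, 1 peak per gene, the one with the highest mean tags. Named were the 8 strongest shared, the 8 with the largest p65 excess and the 8 with the largest p50 excess by the bound of the counting interval nearest to 1, and the 4 strongest of each of 14 gene lists. Of 285 list symbols, 285 matched the gene table (GRCm38.p6), and 284 genes were left after merging synonyms. List medians were placed among 10000 random sets matched in 20 bins of mean tags.

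The ratio calls were tested on simulated data for this comparison with 27323 peaks. Of the 4-fold changes, 50 of 50 were called in each direction, and likewise of the 8-fold changes. Of 27123 unchanged peaks, 0.188% were called leaning to p65 and 0.291% to p50. The simulation drew every tag as independent and left out the repeated tags of these libraries. Its rates therefore cover counting error only, and wrong calls in the data can be more frequent. Alternatives covered the overlap rule, peak strength, scaling, pseudocount, minimum, ratio, promoter distance and distance to the gene. A motif comparison was planned but no genome sequence was used here, so it was not run, nor was the subtraction of input from the merged table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.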

Results

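Genome-wide binding of p65 and p50 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in macrophages grown from the bone marrow of C57BL/6J mice for 7 days. The cells had received 10 ng/mL of Kdo2-lipid A (KLA), the part of bacterial lipopolysaccharide that activates Toll-like receptor 4, for 1 hour. p65 (RelA) is the NF-kB subunit with a transactivation domain, and p50 is a subunit without such a domain. The 2 form the most studied NF-kB dimer, and p50 also forms homodimers. The question the design addresses is where the 2 subunits bind together and where they bind apart. There was 1 library for p65, 1 for p50 and 1 of input DNA, so no difference between the subunits had a replicate check and no p-value is given. The p65 library held 11399666 tags and the p50 library 16042404, and normalised tags are scaled by the authors to a total of 10000000 per library. Intervals cover counting error, or the spread over peaks, and not the spread between cultures.

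The deposited lists of the 2 subunits were of similar length and median tag count after filtering against the same input. The authors' lists held 19145 peaks for p65 and 19807 for p50. The median peak held 50 normalised tags for p65 and 49.9 for p50. Before that filter there were 26702 putative p65 and 58628 putative p50 peaks, of which it removed 26.5% and 65.2%. The median calling score, which counts tags at 1 per position, was 12 for p65 and 37 for p50. The share of all tags that fell in called peaks was 14.5% for p65 and 15.7% for p50, per the file headers. The same loci carried many sites. Lpp, chosen after its values were seen, had the most nearest peaks with 34, of which 14 were called for both subunits, and Tnfaip3, which encodes the NF-kB inhibitor A20, had 24.

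Strong peaks of either subunit mostly overlapped some peak of the other, and weak ones less often. Of the p65 peaks, 60.7% (95% Wilson interval 60.04 to 61.42) overlapped a p50 peak by at least 1 bp. Of the p50 peaks, 58.7% (58.0 to 59.4) overlapped a p65 peak. When the p50 list was moved to random places on the same chromosomes, the mean share of p65 peaks overlapping it was 0.318% over 100 placements. The highest value was 0.444%. Of the strongest 10% of peaks of each list, 92.1% overlapped a peak of the whole other list. When only the top 5000 peaks of each list by score were compared, 55.9% overlapped, so the strongest sites of the subunits were often not the same. Among the weakest 10% it was 34.2% (32.1 to 36.4) for p65 and 29.3% (27.3 to 31.3) for p50. With centres required to lie within 50 bp, 45.99% of p65 peaks had a p50 partner.

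The strongest shared site lay at the promoter of Nfkbia, the gene of the inhibitor IkBa that is induced by NF-kB and retains it in the cytoplasm. This peak (mm10, chromosome 12, 55492608 to 55492855), centred 84 bp upstream of the start site, held 900.0 p65 and 1029 normalised p50 tags. The next was an intron of Asap1 with 855.3 p65 and 876.4 p50 tags. A site 41.4 kb from the microRNA gene Mir101b and one 17.7 kb from Kcnip1 also had a p65 to p50 ratio within 2-fold. The remaining members of the 8 strongest shared sites were uneven. p65 tags exceeded p50 tags 2.53-fold (95% counting interval 2.31 to 2.78) in intron 2 of Sod2, which encodes mitochondrial superoxide dismutase. The excess was 4.69-fold (4.23 to 5.21) at a site 12.7 kb from Ccdc88b, which lies in an endogenous retroviral repeat (RMER4A) and held 4 input tags, above the limit that a count of 0 allows. p50 tags exceeded p65 tags 2.99-fold (2.71 to 3.31) in intron 1 of Spata13. They exceeded them 2.15-fold (1.95 to 2.37) at an intergenic site 46.05 kb from Rbpj, the gene of the DNA-binding effector of Notch signalling, which fell short of 2-fold with equal totals over shared peaks.

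**Figure D1:**
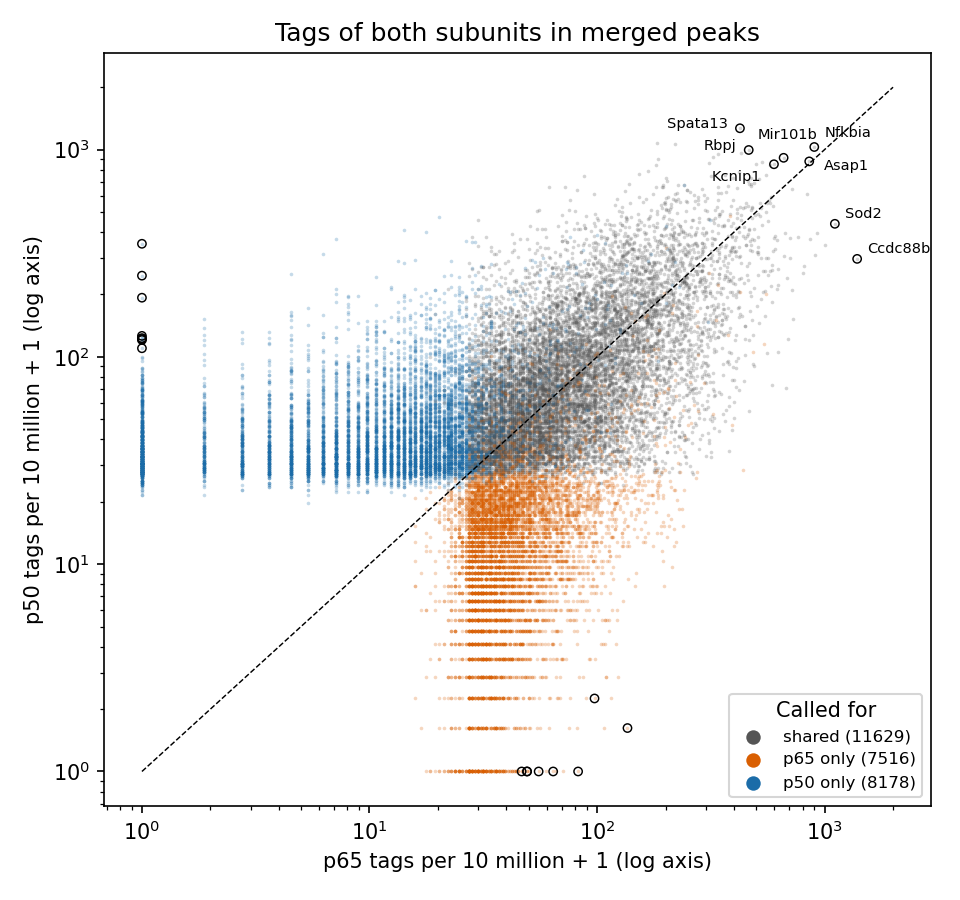
Tags of p50 (vertical, normalised tags plus 1, log axis) against p65 (horizontal, same unit, log axis) in each of the 27323 merged peaks, coloured by the subunits the peak was called for. Circles mark the 24 peaks named by rank, the 8 strongest shared ones with their gene, and the dashed line marks equal tags. The 11629 shared peaks lie around the line, and peaks called for 1 subunit extend to 0 tags of the other.

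Across the 27323 merged peaks, 7346 (26.9%) leaned to p65, 8037 (29.4%) leaned to p50 and 11931 were balanced. A peak was called leaning when its tags differed at least 2-fold. The counting interval, which also had to exclude a ratio of 1, removed 0 of these calls, so the size rule alone set the counts. That interval treats every tag as independent, although many are repeated. With each library's counts scaled to its share left at 1 tag per position, the same rule left 6293 peaks leaning to p65 and 6376 to p50. Of the 11629 shared peaks, 8428 (72.5%) were balanced, 1421 leaned to p65 and 1780 to p50, and their median log2 ratio of p65 to p50 was -0.07 (SD across peaks 0.94). Tags of the 2 subunits had a Spearman correlation of 0.51 across shared peaks, which are not independent replicates.

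Sites with p65 and almost no p50 lay near genes of varied function. The peak in intron 1 of Surf4, a cargo receptor of the endoplasmic reticulum, held 135.1 normalised p65 tags against 1 counted p50 tag, a ratio of 218 (95% counting interval 38.3 to 8615). At 2 counted p50 tags, the site 186.8 kb from Rnf152 had a ratio of 77.2 (20.9 to 647.1). The other peaks of the 8 with the largest p65 excess had 0 p50 tags, and folds were set against a floor of 3 counts in the p50 library, which takes the p65 count as exact. p65 was at least 43.6-fold higher 7.48 kb from Trim27, a ubiquitin ligase gene. It was at least 33.8-fold higher at the promoter of the cadherin gene Cdh22, and at least 29.1-fold higher in intron 1 of Zcchc8. With counting error in both libraries the lower limits of the 95% interval were 34.8, 26.8 and 23.0 for these, and repeated tags make floors and limits too high. Stk3, which encodes a kinase of the Hippo pathway, Clca1 and Dmap1 completed the group.

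The opposite sites, with p50 and 0 p65 tags, reached higher tag counts. The peak nearest to Ptrhd1 (chromosome 12, 4208815 to 4209015), 25.1 kb from its start site, held 350.3 normalised p50 tags, at least 133-fold more than the floor of 3 counts in the p65 library. p50 was at least 93.3-fold higher 64.4 kb from Ccdc80 and at least 73.0-fold higher 4.34 kb from Ccdc8. The promoters of Plgrkt, which encodes a plasminogen receptor, and Ccdc6 each stood among these sites, at least 45.95-fold and 45.48-fold higher. The lower limits of the 95% counting interval were 107.9 for Ptrhd1, 75.5 for Ccdc80, 59.0 for Ccdc8, 37.0 for Plgrkt and 36.6 for Ccdc6, with the same reserve. Tbck, Rxfp2 and Nkx3-2 were the nearest genes of the others.

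Most sites called for 1 subunit still held tags of the other. At the 7516 p65-only peaks the median was 12.5 normalised p50 tags, and 85.4% (84.5 to 86.1) held at least 4 times the p50 genome average. At the 8178 p50-only peaks the median was 12.3 p65 tags, and 79.7% (78.8 to 80.6) held at least 4 times the p65 average. With 4.48 p65 and 2.07 p50 tags for each tag left at 1 per position, few distinct positions can reach this mark. It does not tell weak binding from background. The other subunit had at most 1 counted tag at 4.11% of p65-only and 11.8% of p50-only peaks. These 2 shares are not a like comparison. The p65 library held fewer tags (11399666 against 16042404) and more repeated ones, so low counts come more easily for p65. The promoter of Tnf, an inflammatory cytokine gene, was chosen after its values were seen. Its peak counted as p65 only, with the nearest p50 peak 217 bp away, and held 339.5 p65 and 220.0 p50 tags.

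p50 sites lay near genes' start sites more often than p65 sites. Within 1 kb of a start site were 24.4% (23.5 to 25.3) of p50-only peaks, 12.8% (12.0 to 13.5) of p65-only peaks and 14.7% (14.1 to 15.4) of shared peaks. By tag ratio the shares were 24.3% of p50-leaning, 15.8% of balanced and 11.2% of p65-leaning peaks. The median log2 ratio of the 4667 peaks near start sites was -0.67 (95% bootstrap interval over peaks -0.73 to -0.62), against 0.01 (-0.02 to 0.04) for the 22656 farther ones. Over all peaks, median p50 tags were alike near and far (38.65 and 38.02), while median p65 tags were lower near start sites (30.7 against 39.47). These medians pool peaks of unlike class and strength, so they do not tell which subunit differed. Among peaks called for p65 with like p65 tags, median p50 tags were higher near start sites. The excess was 4.37 (1.87 to 8.13) at 26 to 40 p65 tags and 43.0 (24.3 to 59.2) at 120 to 300. At 300 or more it was 66.4 (-21.8 to 104.1). The difference in log2 ratio was largest below 30 mean tags (-1.36, 2048 of the 4667 peaks), lay between -0.37 and -0.56 from 30 to 300 and was 0.05 (-0.30 to 0.41) at 300 or more. Within p50-only peaks it was 0.05 below 20 mean tags and -0.08 at 20 to 30, so the shift among weak peaks partly reflects which subunit they were called for. Near start sites 41.8% of peaks leaned to p50 and 17.7% to p65, whereas farther away 26.9% leaned to p50 and 28.8% to p65. CpG islands outside annotated gene features held 3.08% of p50-only and 1.06% of p65-only peaks. Peaks in CpG islands over 1 kb from a start site also had a lower log2 ratio than other distant peaks, by a median difference of -0.86. Introns held 45.8% of p65-only, 43.3% of p50-only and 44.4% of shared peaks.

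**Figure D2:**
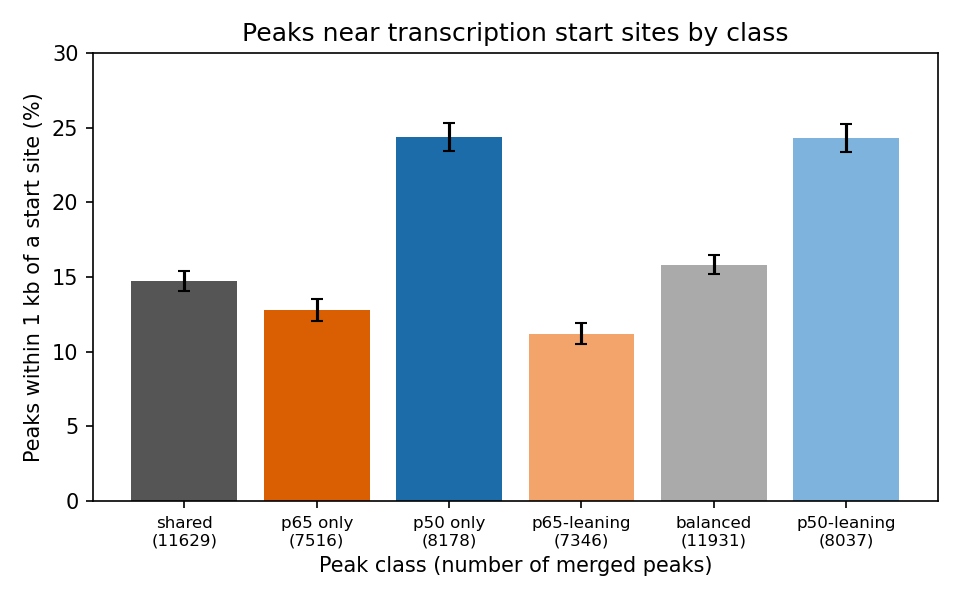
Share of merged peaks within 1 kb of a transcription start site (vertical axis, percent) for each peak class (horizontal axis, number of peaks in brackets), with 95% Wilson intervals over peaks. The p50-only and p50-leaning classes stand at 24.4% and 24.3%, above the other 4.

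Most genes of the lists for NF-kB feedback and inflammation lay nearest to peaks of both subunits. Of 21631 protein-coding genes, 24.4% were nearest to at least 1 peak shared by both subunits. All 16 genes listed as NF-kB feedback and subunits were nearest to such a peak. The same held for 18 of 19 genes listed as inflammatory cytokines and all 14 listed as survival factors. So were 14 of 18 chemokine, 22 of 25 immediate early and AP-1, 19 of 26 Toll-like receptor (TLR) signalling, 16 of 17 inflammatory effector, 17 of 20 antigen presentation and adhesion, 18 of 22 macrophage lineage and 14 of 26 interferon response genes. Among lists of other cells or functions, shared peaks were nearest to 5 of 30 ribosomal protein genes, 8 of 18 T and B cell markers, 4 of 15 neutrophil markers and 2 of 18 liver and neuron genes. Nearest gene is a label by distance, and genes with more surrounding sequence receive more peaks.

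Within the feedback list, the strongest peak was balanced for 11 genes, leaned to p65 for 2 and leaned to p50 for 3. Here and for the lists below, a gene's lean is that of its strongest peak, and its other peaks can differ. The promoters of Tnfaip3 (908.8 p65 and 309.8 normalised p50 tags, log2 ratio 1.55) and Nfkbiz (log2 ratio 1.11), which encodes the nuclear regulator IkBz, were the p65-leaning ones. Tnfaip2 was balanced at -0.53. Among cytokines 12 genes were balanced, 2 leaned to p65 and 4 to p50. The peak 64.7 kb from Il6, in an intron of another annotated transcript, held 685.1 p65 and 239.4 p50 tags. Il1a and Csf1 were balanced, and Il27 leaned to p50 at -1.08 but fell short of the 2-fold rule when ratios were centred (-0.98). No chemokine gene leaned to p65 at its strongest peak, with 12 balanced and 5 leaning to p50. Cxcl10, whose product attracts T cells, had 362.3 p65 and 751.1 p50 tags at its promoter, also under 2-fold after centring (log2 ratio -0.95), while Cxcl1, Cxcl2 and Cxcl16 were balanced.

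TLR signalling genes included 4 leaning to p65, 14 balanced and 1 leaning to p50. Tlr2, a receptor for bacterial lipoproteins, had a log2 ratio of 1.18 at a site 21.4 kb away, and Irak3, Traf3 and Ikbke were balanced. Among inflammatory effectors 5 leaned to p65, 10 were balanced and 2 leaned to p50. Beside Sod2, the site 1.25 kb from Nlrp3, the inflammasome sensor, held 813.2 p65 and 274.9 p50 tags, while Nos2 and Slc2a6 were balanced. Interferon response genes had 6 leaning to p65, 12 balanced and 2 leaning to p50. Stat1 leaned to p50 with 476.2 against 169.3 tags, and Irf1, Mx1 and Gbp5 were balanced.

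Immediate early genes had 3 leaning to p65, 12 balanced and 9 leaning to p50. Ier5 stood at -1.46, whereas Fos, Junb and Dusp2 were balanced. In antigen presentation and adhesion 1 gene leaned to p65, 12 were balanced and 4 leaned to p50. Icam1, a leukocyte adhesion molecule, had 547.3 p50 and 198.2 p65 tags in an intron, and Tapbp, Ciita and Cd44 were balanced. Survival factors had 2 leaning to p65, 11 balanced and 1 leaning to p50, the latter Gadd45a at a site 103.6 kb away with a log2 ratio of -2.31. Birc3, Gadd45b and Bcl2a1a were balanced, and Bcl2a1a is uncertain because near-identical copies can share reads. Macrophage lineage genes had 4 leaning to p65, 10 balanced and 7 leaning to p50. Runx1 leaned to p50 at -1.80 at a site 258.5 kb away, while Spi1, which encodes the macrophage factor PU.1, Adgre1 and Abca1 were balanced. Of the 25 peaks nearest to Runx1, 11 were shared, 10 were p65 only and 4 were p50 only.

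In the comparison lists, ribosomal protein genes had 2 leaning to p65, 4 balanced and 7 leaning to p50. T and B cell markers had 1, 6 and 3 genes in that order, neutrophil markers 4, 4 and 2, and liver and neuron genes 2, 0 and 3. The promoter of Camp, an antimicrobial peptide gene of neutrophils, held 400.9 p65 and 339.1 p50 tags, and Csf3r leaned to p65 at 1.77. Apoa1, a liver lipoprotein gene, was the nearest list gene of a peak 59.6 kb away with 674.5 p50 and 240.4 p65 tags.

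Set beside other genes with peaks of like strength, the lists' balance of p65 and p50 had percentiles from 3.53 to 95.5. Each list's median log2 ratio at the strongest peak per gene was set among 10000 random sets of the same number of genes' peaks matched on mean tags. The median was -0.44 for feedback genes (percentile 39.7), 0.18 for cytokines (94.2), -0.62 for chemokines (19.1) and 0.15 for interferon response (87.5). It was -0.54 for immediate early genes (23.4), 0.26 for TLR signalling (95.5), -0.06 for survival factors (73.5) and -0.55 for antigen presentation (21.9). For effectors it was 0.25 (94.6), for macrophage lineage -0.08 (72.6), for ribosomal proteins -1.22 (3.53), for T and B cell markers -0.41 (36.3), for neutrophil markers 0.76 (95.5) and for liver and neuron genes -1.16 (20.1). Over all peaks of the genes the medians drew closer to 0 for most lists, and lay between -0.35 and 0.36. They were -0.06 for feedback genes, -0.02 for chemokines, -0.06 for ribosomal proteins, -0.01 for T and B cell markers and 0.36 for neutrophil markers, and changed sign for macrophage lineage (0.16) and for liver and neuron genes (0.17). With peaks within 10 kb only, the sign changed for cytokines (-0.21), interferon response (-0.01) and macrophage lineage (0.11), effectors rose to 0.90 and liver and neuron genes fell to -3.89. The median over all merged peaks was -0.10, and centring on it raises each list median by that amount.

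**Figure D3:**
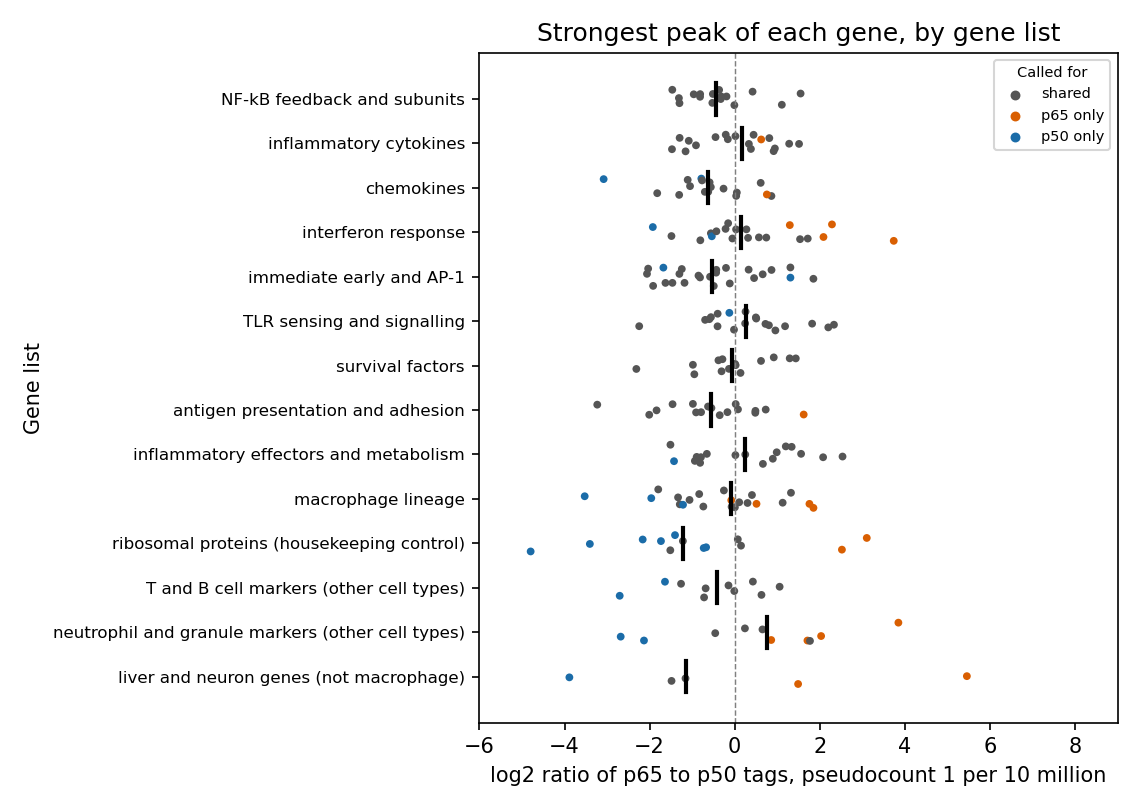
Log2 ratio of p65 to p50 tags (horizontal axis, pseudocount of 1 normalised tag) at the strongest peak of each gene, by gene list (vertical axis). Each point is 1 gene's peak, coloured by the subunits it was called for, spread vertically at random within its list, and the black bar is the list median. Medians lie between -1.22 and 0.76, and every list spans both sides of 0.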

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

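All tests in this part, and the bounds they were held to, were chosen or revised after the result they bear on, or values close to it, had been seen.

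Tags of the input library, which the comparisons do not use, exceeded the limit that a count of 0 allows at 146 p65 peaks (0.763%) and 166 p50 peaks (0.838%). Of the p65 ones, 86 overlapped such a p50 peak. The highest was 26 input tags on an unplaced contig, where p65 had 573.7 and p50 818.5 normalised tags.

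Peaks called for 1 subunit usually held tags of the other, and both lists ended at nearly the same strength. The lower of the 2 shares of such peaks with the other subunit at 4 times its genome average or more was 79.7% (78.8 to 80.6). Many peaks called for 1 subunit may thus be sites of both, with the other below the calling threshold. The mark is low, since the p65 library held 4.48 tags and the p50 library 2.07 for each tag left at 1 per position. Few distinct positions can reach it, so weak binding cannot be told apart from background there. The upper limit of mean input tags was at most 0.202 of the other subunit's median, but the 4-fold filter against input had already kept it under 0.749, so this says little on input as a source. The lists' own thresholds did not set the common lower end, since the lowest p50 score was 11 against a threshold of 8, although 8.34% of p65 peaks lay at theirs of 6. The lowest called peaks differed by 0.1 normalised tags, and scaled to the input total both lists ended at 6.1 tags where the input had 0, at 7.1 where it had 1 and at 10.4 where it had 2, so the filter against the shared shallow input is a candidate source of this end.

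By tag ratio peaks near start sites leaned to p50. Medians pooled over all peaks showed fewer p65 tags and like p50 tags there, whereas p65 peaks of like p65 tags held more p50 tags up to 300 p65 tags. Lower mean tags alone do not account for the lean. The median log2 ratio was -0.70 (-0.78 to -0.61) below distal peaks matched on mean tags, against -0.68 unmatched. The shift was -1.36 below 30 mean tags, -0.37 at 120 to 300 and 0.05 (-0.30 to 0.41) at 300 or more. Within p50-only peaks it was 0.05 below 20 mean tags and -0.08 at 20 to 30. The large shift among weak peaks thus partly reflects which subunit they were called for, and matching on mean tags does not remove this. A constant p50 background does not account for the lean at peaks called for p65. The p50 excess near start sites was 43.0 normalised tags (24.3 to 59.2) at 120 to 300 p65 tags against 4.37 (1.87 to 8.13) at 26 to 40, with log2 shifts of -0.39 and -0.32. At p50-only peaks such a background cannot be told apart from binding, because no group of mean tags showed a clear excess near start sites. The interval spanned both signs in each group. The excess was -0.39 (-1.47 to 0.49) below 20 mean tags and 4.005 (-4.21 to 14.8) at 60 to 120, the strongest group with at least 20 peaks near start sites. Better recovery of GC-rich fragments in the p50 than in the p65 library remains a candidate explanation, since 239 CpG island peaks away from start sites also shifted to p50, by -0.86 (-1.09 to -0.73), but GC content was not measured, such islands could be unannotated start sites, and a preference of p50 for promoters or less p65 there stays open with 1 library per subunit.

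Peaks in L1Md_F, L1Md_F2 and L1Md_F3, a family of LINE-1 retrotransposons, leaned to p65, with 146 of 166 called for p65 only and a median log2 ratio of 2.62 (2.34 to 2.78). Reads shared between copies stay open, since the other L1Md subfamilies had 8 peaks, too few to decide, with a median of 1.73 (0.742 to 2.04). PCR duplicates would lower its score per tag, which was 5.63% (-0.0498 to 8.61) higher than at other p65-only peaks with an interval that holds 0 but no large fall. Copies missing from the genome build cannot be told apart from binding, because 6 of the 146 peaks had an input tag, 1.07 times the share elsewhere with an interval of 0.496 to 2.27. The filter against input also limits this count. The lowest called p65 peak with 2 input tags held 44.7 normalised tags, above the family's median of 41.2. Binding of p65 or of a protein recognised by its antibody stays open and untested.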

How the results depend on the processing

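Added after the data were seen were the scaling of counts to the share left at 1 tag per position and the adjusted exact binomial test. So were the removal of peaks with over 3 input tags and the restriction to at least 60 mean tags. Of 88 alternatives to the main results, 53 left the value within its interval or the count within 1.5-fold. Overlap moved with its definition. With 50% of each peak required it was 57.2% of p65 and 55.3% of p50 peaks, with centres within 50 bp 45.99% and 44.4%, and within 500 bp 64.5% and 62.3%. At or above the median score 59.8% of p50 peaks overlapped, with equal numbers of top peaks 59.9% of both, and in the top 5000 55.9%. A ratio of at least 4 left 3437 p65-leaning and 3847 p50-leaning peaks, by construction. The adjusted binomial test, which compares the libraries and not the conditions, called the same 7346 and 8037 peaks, which is no separate support because the size rule set the calls. With each library's counts scaled to its share left at 1 tag per position, 6293 and 6376 were left. This scaling kept every ratio and only widened the counting intervals. Repeated tags were not removed peak by peak. The share of leaning peaks that leaned to p65 was 47.8%, and 51.3% after centring or 51.7% with equal totals over shared peaks, so which side is larger depends on the scaling.

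The p50-only and p50-leaning classes stayed above the other 4 near start sites at each distance. Within 500 bp lay 10.9% of shared, 9.09% of p65-only, 19.4% of p50-only, 7.76% of p65-leaning, 11.8% of balanced and 19.4% of p50-leaning peaks, and within 2.5 kb 21.3%, 19.6%, 31.6%, 17.8%, 22.5% and 31.6%. At or above the median score, p65-only peaks stood at 9.18%, p65-leaning at 8.73%, balanced at 14.3% and p50-leaning at 22.1%, and with at least 60 tags at 9.86%, 8.65%, 14.1% and 21.3%, and the cause was not tested. The median log2 ratio near start sites was -0.57 after centring, -0.56 with equal totals and -0.61 with a pseudocount of 5. Shared peaks within 10 kb were nearest to 13 macrophage lineage genes and 0 liver and neuron genes, against 14.8% of protein-coding genes.

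For 78 named peaks, settings that can change the log2 ratio (centring, equal totals, pseudocount) ended 6 of 234 calls and the 4-fold rule 22 of 78, with the same direction. The other settings leave the ratio fixed by construction and say nothing about its stability, and the removal of peaks with over 3 input tags left out the 3 named peaks of Ccdc88b, Fos and Ciita. List medians rest on the strongest peak per gene, and over all peaks that of feedback genes left its interval (-0.06). No paired analysis was possible because each group has 1 library. The motif alternatives and input subtraction were not run.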

Other observations

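The tests in this part were chosen after the data were seen, and the genes named here outside the fixed rule were chosen after their values were seen.

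Several genes had many peaks of both kinds. Of 10124 genes nearest to a peak, 5527 had at least 2 and 340 at least 10, and 2152 had both a p65-leaning and a p50-leaning peak. Trps1 had 30 peaks, Dock10 and Foxp1 29 each, and Maf, a macrophage transcription factor gene, 27. Prdm1, which encodes the repressor Blimp-1, and Cd44, a hyaluronan receptor gene, had 26 each. Examples of leaning peaks within gene lists were the promoter of Saa3, an acute phase protein gene, with 442.1 p65 and 75.4 normalised p50 tags, and that of Gbp2, an interferon-induced GTPase gene, with 211.4 and 63.6. In the other direction, a site 5.44 kb from Itgam, the gene of integrin CD11b, had 16.7 p65 and 202.6 p50 tags.

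Other repeats went both ways. The 51 peaks in MTA_Mm elements, a family of endogenous retroviral repeats, had a median log2 ratio of -1.18 (-1.66 to -0.64), and the 26 in RLTR14 -0.996 (-1.94 to -0.47). The 27 in B1F leaned to p65 with 1.85 (0.20 to 2.53), and medians were 0.52 (0.35 to 0.80) for DNA repeats and 0.20 (0.08 to 0.48) for SINE.

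It was asked whether the lean belongs to the locus, so that neighbouring peaks would share it. Across 4950 pairs of neighbouring peaks 1 to 5 kb apart, the Spearman correlation of log2 ratios was 0.0721 (0.0490 to 0.0979), which is small. Among pairs with at least 40 mean tags each it was 0.14 (0.0914 to 0.194). Counting noise in the ratios lowers such a correlation, and the highest value it could reach here was not estimated. A lean shared by whole loci is therefore not excluded.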
